A study of Oryza sativa with 18 samples.

How the data were processed

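R-loops are RNA-DNA hybrids with a displaced DNA strand. In the assay used here (ISRH-seq), sonicated genomic DNA of wild-type rice seedlings is treated with RNase H and DNA polymerase I, which replaces the hybrid strand with biotin-labelled DNA, and the labelled strand is captured and sequenced as single-stranded libraries, per the labels' protocols. The 18 libraries comprise 13 that are titled by the amount of input DNA (2 libraries each at 8, 5, 3 and 1 µg, 500 ng and 250 ng, and 1 at 100 ng), 1 titled RNaseH, 2 titled salt and 2 titled CK(salt). The salt labels give 150 mM NaCl, and the treatment label reads 3 days for the salt and also for the CK(salt) libraries. The titles were used to group them, and the conflict in the treatment label was not resolved. The protocol's list of amounts leaves out 1 µg, which is taken from the titles. The step at which RNase H was added to the RNaseH library and the input amounts of that library and of the salt and CK(salt) libraries were not given in the sources used here. Nothing in the labels says whether libraries of 1 group came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

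Reads were aligned with Bowtie2 and peaks were called with MACS2 2.1.4, per the submitters' processing notes. The authors deposited 1 peak list per library in the narrowPeak layout, without a header. In each list the deposited score is 10 times the −log10 q-value without decimals. The deposited fold is the ratio of summit pileup to the local background that the caller estimated, and the deposited p-value and q-value of each summit are on the −log10 scale. The lists carry no read counts. The lowest −log10 q lay just above 2 (a q-value of 0.01) in 17 libraries. Whether a control library entered the peak calls, how duplicates and multiply aligned reads were treated and which genome build was used is not given in the sources used here. A fold or score belongs to its peak in its own list and was used only to describe, rank or filter peaks within that list.

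All 812930 peaks lay on the 12 nuclear chromosomes and 0 of them overlapped another peak of the same list, so merging rows and limiting the chromosomes changed nothing. Coordinates are those of the deposited lists, given 1-based. The gene table at hand is of assembly ASM3414082v1, in which genes of chromosome 9 reach 27.5 Mb, whereas peaks on that chromosome end at 22.9 Mb in these lists. Coordinates of different builds were not joined. Every planned result that needs genes or sequence was therefore not run, namely the share of peaks in genes, the genes gained and lost under salt, the feature enrichment, the sequence composition, the gene lists and the named genes. The rule for named genes, fixed before the data were examined, was applied to regions instead. It takes the 10 regions gained and the 10 lost with the highest lower-of-2 percentile of the q score within the libraries that hold the peak, the 10 regions present in all 13 input lists with the highest median percentile, and the 10 highest-scored peaks of the RNaseH library. Clusters of RNaseH peaks within 100 kb were formed after the lists were seen.

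Depth was read from the lists. Fold and p-value together fix the summit pileup, a whole number, and the local background, because the caller's fold is (pileup + 1)/(background + 1) and its p-value is a Poisson tail. Both were solved for at least 99.99% of the summits of every list, with a tolerance of 0.0002 on the −log10 scale. The most frequent background of a list is its genome-wide background coverage, and 0% of summits lay below it. It serves here as the measure of depth. Lists were thinned to a lower depth by drawing each pileup from a binomial distribution with its background scaled alike, and by applying the lowest −log10 p of the shallower list. Peak names carry library codes that form 9 runs of consecutive numbers, which may follow preparation or sequencing order, although no label says so. They were used as a possible batch, and relations were computed again within the runs. The peak names also carry the word single in 8 µg replicate 1, merge in 8 µg replicate 2 and CK(salt) replicate 1, and uniq in the other 11 input libraries and the RNaseH library. The other 3 libraries carry none of these words, whose meaning is not given in the sources used here.

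Peaks shared at least 1 bp to count as overlapping. Lists were compared by the base-pair Jaccard index, which is the number of shared bases over the bases in either list. Across the 13 input libraries, log2 peak number, log2 covered bases, median peak width, median fold and recovery of the 8 µg regions were each set against log2 input amount by Pearson's r and Spearman's rho, with two-sided permutation tests of 100000 resamples and Benjamini-Hochberg adjustment over these 5 relations. Width, fold and recovery were not log-transformed. Salt and CK(salt) lists were merged into regions. A region was gained if it had a peak in both salt libraries and in neither CK(salt) library, and lost in the reverse case. Shares from a single list are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Alternatives fixed beforehand were a minimum −log10 q of 5, lists cut to equal length, 50% reciprocal overlap, merging within 500 bp, omission of each replicate number and library, and a block by replicate number. Thinning, the relation at constant background the relations within code runs and those among the 11 input libraries with uniq were added after seeing the data.

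Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated data. For the depth estimate, pileup and background were recovered for 100% of 4982 simulated summits, and the expected number of peaks after thinning 20000 simulated sites was 99.8% of the number drawn. The draw followed the same binomial model with a constant background. It checked the computation, not whether a thinned list matches the peaks called in a real shallower library. For the comparison of salt with CK(salt), 100% of the planted gained and 100% of the planted lost regions were found among 12000 regions, with 0 false calls. Unplanted regions had a peak in every simulated list, so false calls from peaks that a list misses by chance were not tested. For the relations over input amount, 5.3% of 1000 null sets fell under 0.05.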

Results

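Peak lists of R-loops in rice seedlings were examined for 18 libraries, which address how the profile depends on the amount of input DNA, what is left in an RNase H control and how the profile differs after salt treatment. The lists held from 123 peaks in the library labelled RNaseH to 70518 peaks in 8 µg replicate 1. Outside the RNaseH library, median peak widths ran from 273 bp at 100 ng to 514 bp in 250 ng replicate 2. Depth differed between libraries. Background coverage, in fragments per position, was 11.4 and 12.7 in the 8 µg libraries, 4.82 to 7.84 in the libraries from 5 µg to 250 ng, 0.881 at 100 ng and 3.1 in the RNaseH library. It was 6.74 and 3.88 in the salt libraries and 8.60 and 4.30 in the CK(salt) libraries.

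Outside the RNaseH library, R-loop peaks were spread over all 12 chromosomes with a similar ranking in each library. Chromosome 3 had the highest peak density in 17 of the 17 libraries other than RNaseH, and chromosomes 1, 2 and 3 were the densest 3 in all 17. Chromosome 12 had the lowest density in 13 of them, and chromosomes 11 and 12 were among the lowest 3 in all 17. In the 8 µg libraries the density was 208 ± 10.7 peaks per Mb on chromosome 3 and 160.2 ± 6.06 on chromosome 12 (SD, n = 2). In the 250 ng libraries it was 139 ± 4.25 and 97.1 ± 1.03 peaks per Mb (SD, n = 2), respectively.

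The 13 input lists merged into 87833 regions. Of these, 10128 (11.5%) had a peak in all 13 libraries, whereas 12758 (14.5%) had a peak in 1 library only. The highest-ranked region common to all 13 lists was on chromosome 1 from 33520462 to 33522461, with a median percentile of 99.998 for its peak score. Next came chromosome 12 from 8530977 to 8533334, chromosome 11 from 16542975 to 16544628 and chromosome 10 from 8053296 to 8054497. Of the 10 highest-ranked common regions, those on chromosome 12 at 20517386 to 20518313, 20558668 to 20559486 and 20631366 to 20633305 lay close together. Of these 10 regions, 8 overlapped a peak of the RNaseH library, the first 3 among them. Most of this ranking thus consists of places that also had a peak in the RNaseH library.

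Libraries made from more input DNA held more peaks. The number was 68237 ± 3227 at 8 µg, 53425 ± 6722 at 5 µg, 53506 ± 7351 at 3 µg, 52713 ± 3702 at 1 µg, 46070 ± 340 at 500 ng and 44497 ± 1064 at 250 ng (SD, n = 2 each). The single 100 ng library had 14845 peaks. The groups from 5 to 1 µg differed from one another by less than the spread within them. Log2 peak number rose with log2 input (r = 0.75, permutation p = 9.0e-05, adjusted p = 0.00045; rho = 0.903, p = 6.0e-05). Without the 100 ng library and 1 of the 8 µg libraries, r was 0.775 or 0.767, depending on which of them was left out (permutation p = 0.00622 and 0.00499). The 8 µg libraries also differ from the other 11 in the words of their peak names, and among those 11 r was 0.688 (permutation p = 0.00141, adjusted p = 0.00352). Background coverage rose with input as well (r = 0.733, permutation p = 0.00052, rho = 0.77, p = 0.00324). Without the 100 ng library and 8 µg replicate 1, this r was 0.578 (permutation p = 0.05). Peak number in turn rose with background coverage (r = 0.973, permutation p = 5.0e-05, rho = 0.83, p = 0.00066). That r was 0.893 (permutation p = 0.00028) without the 100 ng library. At constant background coverage the relation of peak number to input gave r = 0.244 (permutation p = 0.42) over the 13 libraries and r = 0.643 (p = 0.0239) without the 100 ng library. Within the 3 runs of consecutive library codes that hold more than 1 amount, 8 libraries in all, r was 0.845 (exact permutation p = 0.0417, adjusted p = 0.0926).

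**Figure D1:**
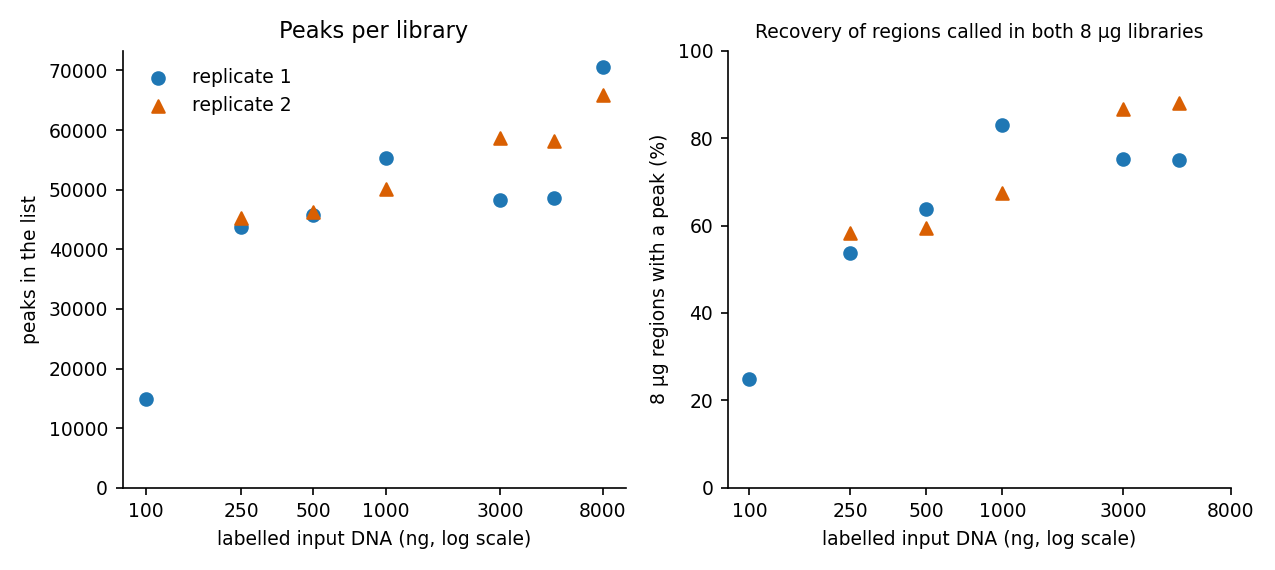
Number of peaks (left) and percentage of the regions called in both 8 µg libraries that had a peak (right), against the labelled amount of input DNA on a log scale. Each point is 1 library, with circles for replicate 1 and triangles for replicate 2. The 100 ng library has 14845 peaks and 25.0% recovery, below every other library.

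The covered length followed the peak number less closely. It was 35.7 ± 1.39 Mb at 8 µg and 26.1 ± 1.37 Mb at 250 ng (SD, n = 2), and 4.68 Mb at 100 ng. The relation to input (r = 0.594, permutation p = 0.00883, adjusted p = 0.0147; rho = 0.604, p = 0.0314, adjusted p = 0.0524) rested on the extreme libraries, since r was 0.192 or 0.231 (permutation p = 0.583 and 0.515) without the 100 ng and 1 of the 8 µg libraries. Within code runs r was -0.555 (exact permutation p = 0.444). Peaks at 500 and 250 ng had a higher median width and a lower median fold than those at 5 and 3 µg in every library. The median width was 396 ± 24.0 bp at 5 µg, 394 ± 5.66 bp at 3 µg, 487 ± 24.0 bp at 500 ng and 502.5 ± 16.3 bp at 250 ng, and the median fold was 5.37 ± 0.283, 5.30 ± 0.259, 4.58 ± 0.558 and 3.92 ± 0.208 (SD, n = 2 each). In the mean, the 8 and 1 µg groups lay between these. Their median widths were 433.5 ± 3.54 and 450.5 ± 40.3 bp, and their median folds 4.73 ± 0.319 and 4.69 ± 0.259 (SD, n = 2 each). The highest amount thus had neither the narrowest peaks nor the highest fold. The 100 ng library, at the lowest amount, had a median width of 273 bp and a median fold of 6.07, opposite to 500 and 250 ng. Over all 13 libraries no relation to input was detected for either measure (width r = -0.0835, permutation p = 0.793, rho = -0.316, p = 0.289; fold r = 0.195, permutation p = 0.522, rho = 0.238, p = 0.432; adjusted p = 0.793 and 0.652). Without the 100 ng and 1 of the 8 µg libraries, width gave r = -0.836 or -0.849 (permutation p = 0.00328 and 0.00277) and fold gave r = 0.824 or 0.71 (permutation p = 0.00253 and 0.0183). Within code runs the values were -0.874 for width (exact permutation p = 0.0556) and 0.758 for fold (exact permutation p = 0.0972).

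Strong 8 µg regions were recovered at every amount, and weak ones less often. A total of 57109 regions had a peak in both 8 µg libraries. Of these, 81.6 ± 9.16% had a peak at 5 µg, 81.0 ± 8.13% at 3 µg, 75.2 ± 11% at 1 µg, 61.6 ± 3.07% at 500 ng and 56.1 ± 3.32% at 250 ng (SD, n = 2 each). The 100 ng library held 25.0% of them. In the strongest decile of these regions the recovery was 99.99 ± 0.0137% at 5 µg and 94.6 ± 3.48% at 250 ng (SD, n = 2), and 89.4% at 100 ng. In the weakest decile it was 40.1 ± 18.9%, 29.7 ± 1.73% and 1.11%. Of the 100 ng peaks, 98.8% lay in regions called in both 8 µg libraries, compared with 69.9% and 73.3% of the peaks of the 250 ng libraries. Recovery rose with input over the 11 libraries (r = 0.88, permutation p = 0.00021, adjusted p = 0.000525; rho = 0.897, p = 0.00056). It gave r = 0.9 or 0.811 without the 100 ng and 1 of the 5 µg libraries (exact permutation p = 0.00198 and 0.0116), and 0.924 within code runs (exact permutation p = 0.0278, adjusted p = 0.0926). The call was also lost without replicate 2 (r = 0.78, adjusted exact permutation p = 0.0929), and with equally long lists r was 0.694.

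Libraries of 1 amount shared more bases than libraries paired at random, by a small margin. The mean Jaccard index of the 6 same-amount pairs was 0.596, compared with a mean of 0.501 over all ways to pair the 12 libraries, of which 470 gave a value as high (one-sided exact p = 0.0452). The index was 0.669 for the 8 µg pair, 0.585 at 5 µg, 0.575 at 3 µg, 0.501 at 1 µg, 0.605 at 500 ng and 0.641 at 250 ng. The 250 ng pair is the only one of the 6 within 1 run of library codes. Some pairs of different amounts were closer. Replicate 1 at 5 µg and at 3 µg, which share a run of library codes, had an index of 0.679, and replicate 2 at 5 µg and at 3 µg, of another run, had 0.711. The 1 µg libraries fell apart. Replicate 1 had an index of 0.609 to 0.658 with the 6 libraries of 3 µg and more, whereas replicate 2 had 0.607 to 0.657 with the 4 libraries of 500 and 250 ng. Replicate 1 shares a run of library codes with replicate 2 at 5 and 3 µg, and replicate 2 with 500 ng replicate 2. The call was lost when lists were cut to equal length (0.603, one-sided exact p = 0.0554) and when the share of overlapping peaks replaced the Jaccard index (0.86, one-sided exact p = 0.103). It was also lost without the 8 µg pair (0.581), the 500 ng pair (0.594) or the 250 ng pair (0.587), with one-sided exact p = 0.121, 0.0656 and 0.154. No difference in peak number was detected between replicate 1 and replicate 2 (mean log2 ratio -0.06, two-sided exact sign-flip p = 0.406, higher in replicate 1 at 2 of 6 amounts), where 0.0313 is the smallest p that 6 pairs allow.

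**Figure D2:**
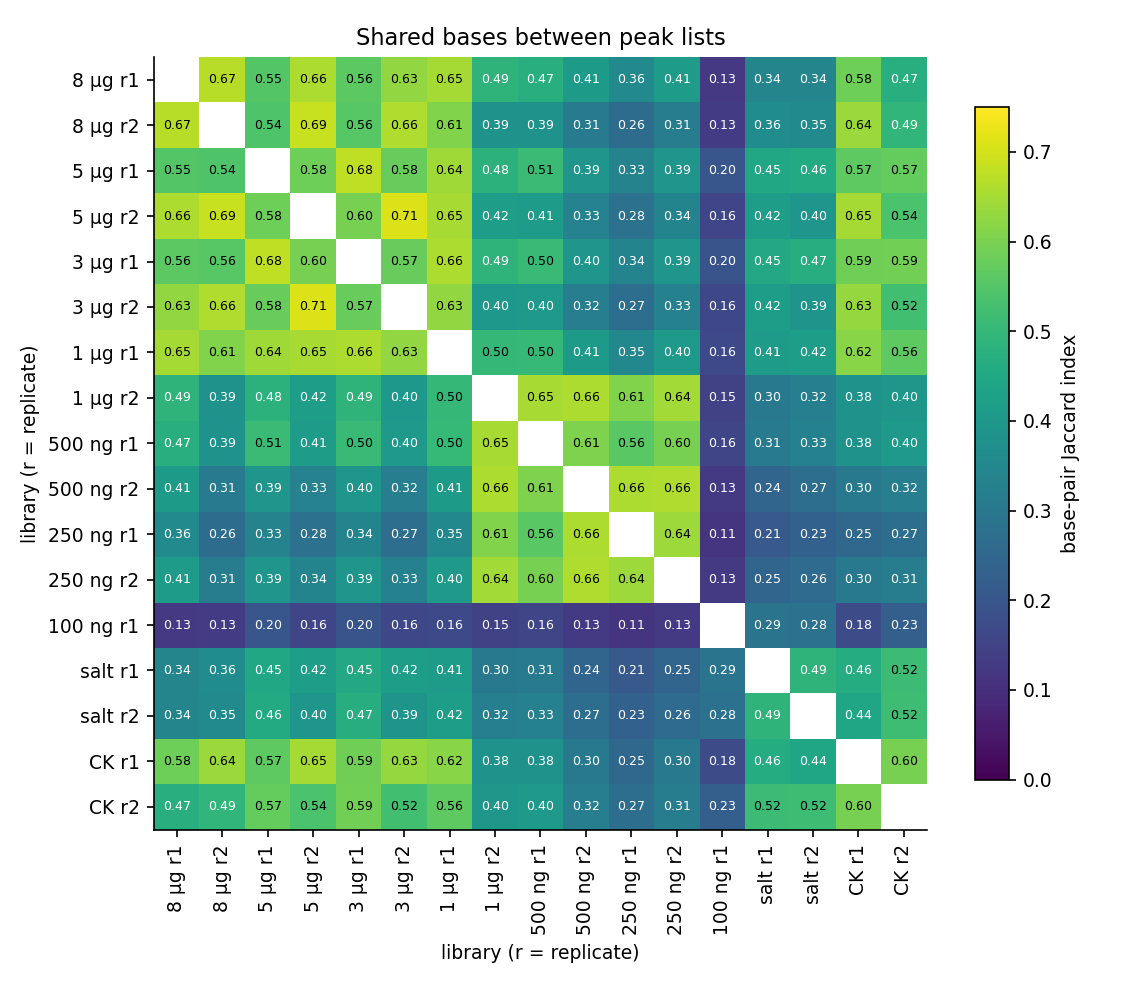
Base-pair Jaccard index between every pair of peak lists other than RNaseH, with rows and columns as libraries (r marks the replicate) and colour running from 0 to 0.75. The index is 0.501 between the 1 µg libraries and 0.711 between replicate 2 at 5 µg and at 3 µg.

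RNase H degrades the RNA strand of an RNA-DNA hybrid. The library labelled RNaseH held 123 peaks covering 0.0844 Mb. The 13 input libraries held 14845 to 70518 peaks. When the 12 input lists of higher depth were thinned to the depth of this library, 21244 to 45264 peaks remained. The residual peaks were unevenly placed, with 47 (38.2%) on chromosome 12, 20 on chromosome 1, 18 on chromosome 9 and 0 on chromosome 6. The input lists had 6.32 ± 0.289% of their peaks on chromosome 12 and 8.46 ± 0.099% on chromosome 6 (SD, n = 13). Residual peaks within 100 kb of each other formed 12 clusters with 86 peaks. The largest cluster had 27 peaks on chromosome 12 from 20469862 to 20667795, followed by 14 peaks on chromosome 9 from 4678601 to 4732358, 9 peaks on chromosome 12 from 13342326 to 13410748 and 9 peaks on chromosome 1 from 33516480 to 33584889.

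The same places carried peaks in the other libraries. Of the 123 peaks, 119 (96.7%, 95% interval 91.9 to 99.1%) overlapped a region of at least 1 input list, and shuffled positions gave 28.6%. A single input list overlapped 82.7 ± 7.05% of them (SD, n = 13), against 15.1% for shuffled positions. Conversely, 68 of the 10128 regions common to all input lists (0.671%, interval 0.522 to 0.850%) overlapped a residual peak, but 8 of the 10 highest-ranked ones did. Of all 123 peaks, 75 (61.0%, interval 51.8 to 69.6%) overlapped a region common to all 13 input lists. The 10 highest-scored residual peaks had a peak in all 17 other libraries. The first of them lay on chromosome 12 from 20558740 to 20559448 with a fold of 15.1, the second on chromosome 10 from 2756592 to 2757372 with a fold of 11.9, and the third on chromosome 11 from 12164497 to 12164834 with a fold of 22.2. Local background was at least 5 times the genome-wide level at 52 residual peaks (42.3%, interval 33.4 to 51.5%). It was so at 0.424% of peaks or fewer in each other list. In number these were 45 to 72 peaks per list, so much of the contrast in share comes from the length of the lists. A single RNaseH library allows no test.

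**Figure D3:**
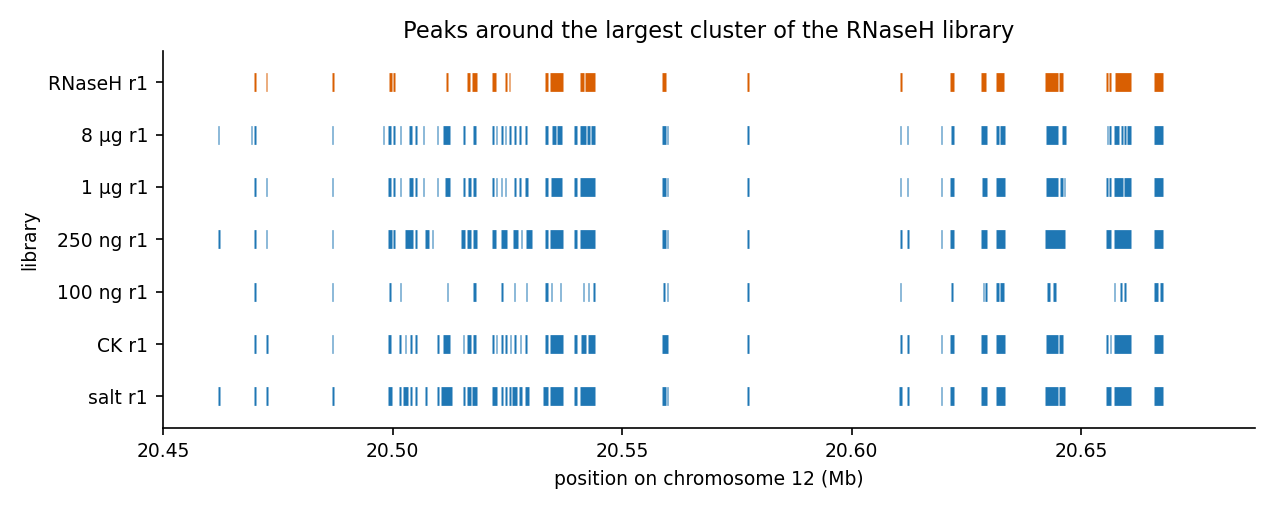
Peaks between 20.45 and 20.69 Mb of chromosome 12 in the RNaseH library (top row, orange) and 6 other libraries (blue), drawn to scale, with each bar spanning 1 peak. The RNaseH library has 27 peaks in this window, 8 µg replicate 1 has 49 and salt replicate 1 has 40.

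Seedlings labelled as salt-treated gave fewer and narrower peaks than their CK(salt) controls. The salt lists held 32861 and 35907 peaks (34384 ± 2154; SD, n = 2), and the CK(salt) lists held 51710 and 40592 (46151 ± 7862; SD, n = 2). The difference in mean log2 peak number was -0.42, and both salt libraries lay below both controls (two-sided exact permutation p = 0.33, which is the smallest p that 2 against 2 libraries allow). The covered length was 13.6 ± 0.0905 Mb under salt and 22.5 ± 4.93 Mb in CK(salt), the median width was 333.5 ± 26.2 and 414 ± 18.4 bp, and the median fold was 4.31 ± 0.429 and 4.98 ± 0.168 (SD, n = 2 each), each with an exact permutation p of 0.33. Without CK(salt) replicate 1, whose peak names alone among these 4 libraries carry the word merge, the difference was -0.24. By replicate number, salt libraries had 63.5% and 88.5% of the peaks of the CK(salt) library.

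Few regions were gained under salt and many more were lost. Of the 58496 merged regions, 22988 (39.3%) had a peak in all 4 libraries, 161 were gained and 4710 were lost. The counts depend on the settings, with 83 gained at a −log10 q of at least 5 and 1572 at 50% reciprocal overlap. With 1 of the 4 libraries left out, 294 to 2478 were gained and 7124 to 14361 lost, as fewer libraries then have to agree. The lost regions were 12.8% (95% interval 12.5 to 13.2%) of the 36701 regions present in both CK(salt) libraries, and the gained ones 0.661% (interval 0.563 to 0.771%) of the 24363 present in both salt libraries. The other divisions of the 4 libraries into pairs separated 2016 and 680 regions (replicate 1 against replicate 2) and 219 and 2092 regions (crossed pairs). Losses were found on every chromosome, from 11.3% of the CK(salt) regions on chromosome 12 to 13.5% on chromosome 4. They fell with peak strength, from 43.4% of regions in the weakest decile of CK(salt) to 0 of the 3670 regions in the strongest decile. Libraries of 1 group also shared weak peaks less often. CK(salt) replicate 2 held 26.0% of the weakest and 99.96% of the strongest decile of replicate 1 peaks, and 68.0% and 99.98% in the reverse direction. Between the salt libraries these shares were 34.9 to 35.2% and 97.7 to 99.7%. The gradient is thus not particular to salt. With lists cut to the 32861 best-scored peaks each, 998 regions were gained and 1641 lost, and the replicate 1 against replicate 2 division separated 1314 and 1385 and the crossed pairs 789 and 903. Same-numbered salt and CK(salt) libraries share a run of library codes, so the division by replicate number also follows these runs. The salt libraries had a Jaccard index of 0.487 with each other. Each had more with CK(salt) replicate 2 (0.515 and 0.518) and less with CK(salt) replicate 1 (0.464 and 0.440). The CK(salt) libraries had 0.596 with each other, so by shared bases the salt libraries did not group apart from the controls.

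**Figure D4:**
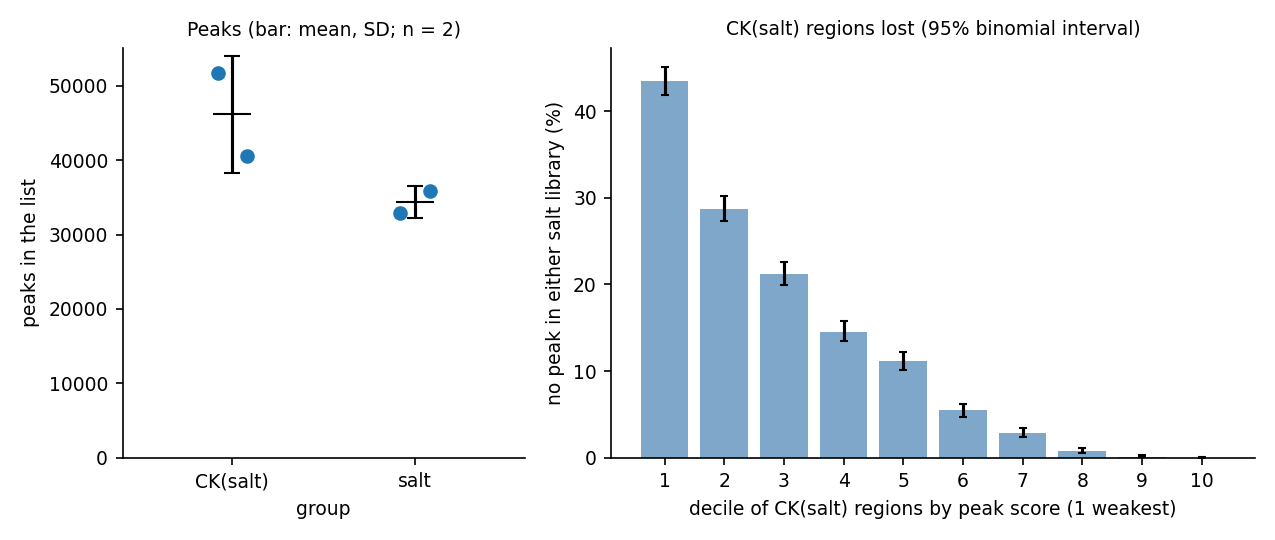
Left, peaks per library in CK(salt) and salt, with points for libraries and bars for mean and SD. Right, percentage of regions with a peak in both CK(salt) libraries that had none in either salt library, by decile of peak score, with 95% binomial intervals. The percentage falls from 43.4% in decile 1 to 0% in decile 10.

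Regions gained under salt with the highest scores were 221 to 352 bp long, and 4 of the 10 lay on chromosome 12. Of all 161 gained regions, 18 lay on chromosome 12 and 24, the most, on chromosome 4, and 6 overlapped a peak of the RNaseH library, compared with 1 of the 4710 lost regions. The first lay on chromosome 12 from 21960260 to 21960510, with folds of 12.8 and 13.5 in the salt libraries, and overlapped a peak of the RNaseH library, as did the seventh, on chromosome 3 from 26607009 to 26607360. The second lay on chromosome 12 from 13403659 to 13403879 (folds of 6.36 and 8.97), within a cluster of RNaseH peaks and 4.18 kb from the nearest of them. The third lay on chromosome 12 from 20461999 to 20462289 (11.2 and 15.2), at 7.57 kb from the nearest RNaseH peak. The region on chromosome 6 from 11347696 to 11347929 had folds of 11.5 and 12.7. All 10 highest-scored gained regions had a peak in 3 to 12 of the 13 input lists. In all, 155 of the 161 gained regions (96.3%) had a peak in at least 1 input list, so that 6 had a peak in none of them. Of these 6, the region on chromosome 7 from 23277373 to 23277597 ranked at percentile 95.1 or higher in both salt libraries; it was picked out after its values were seen.

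The highest-scored lost region was on chromosome 4 from 34146259 to 34146636, with folds of 7.56 and 7.83 in the CK(salt) libraries. It was followed by chromosome 3 from 17021042 to 17022159 (8.99 and 9.86), chromosome 1 from 11260953 to 11261321 (8.92 and 11.2), chromosome 7 from 24177114 to 24177549 (6.94 and 6.49) and chromosome 7 from 23547842 to 23548258 (10.6 and 8.12). The regions on chromosome 3 and on chromosome 5 from 9537579 to 9538134 had a peak in all 13 input lists. Lost regions had a peak in 8.26 ± 3.23 of the 13 input lists (SD over 4710 regions), gained ones in 6.01 ± 3.69 (SD over 161 regions) and those of all 4 libraries in 11.5 ± 1.92 (SD over 22988 regions).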

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

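Thinning, constant background, code runs and words in peak names were tests chosen after seeing the data. Of 150 alternatives over 12 results, 113 left direction and side of the threshold (or a count within 1.5 times) in place, among them all those for replicate 1 against replicate 2 and for salt against CK(salt) peak number (log2 difference -0.65 to -0.18, with no test able to pass). Peak number against input lost its call at constant background coverage (r = 0.244), where the 100 ng library is low in both, and within code runs (0.845, adjusted exact permutation p = 0.0926), and kept it with 12 lists thinned to 1 depth (r = 0.821). Covered bases ran from r = 0.381, without the 100 ng library, to 0.728 with libraries or replicate numbers left out, lost the call without the 100 ng library or replicate 2 and among the 11 libraries with uniq in their peak names (0.512), and reversed within code runs (-0.555). Width ran from -0.861 to 0.205 and fold from -0.104 to 0.855 with libraries left out, with calls (adjusted permutation p = 0.0061 and 0.019; range 0.0061 to 0.974) only without the 100 ng library or without replicate 1 and reversals without replicate 2 and, for width, without either 250 ng library. Recovery ran from 0.78 (without replicate 2, call lost, adjusted exact permutation p = 0.0929) to 0.968 with libraries or replicate numbers left out, gave 0.694 with equal lengths, and lost its call within code runs (0.924, adjusted exact permutation p = 0.0926). Only 72 permutations are possible within code runs, and r there was not below the reported one for recovery (0.88) or peak number (0.751). Concordance lost its call with equal lengths (0.603), with the share of the shorter list (0.86) and without the 8 µg (0.581), 500 ng (0.594) or 250 ng pair (0.587), and kept it without the 1 µg pair (0.615; exact p = 0.0148 to 0.154 over its alternatives). Regions gained numbered 83 with −log10 q of at least 5, 998 with equal lengths and 1572 with 50% reciprocal overlap, and regions lost 1641 with equal lengths. Left-out libraries gave 294 to 5929 gained and 7124 to 21554 lost regions, since fewer libraries then have to agree. The cause of the other changes was not tested. Same-numbered libraries did not deviate together as a whole over 378 windows of 1 Mb. The r was 0.0333 between salt and CK(salt), which share code runs, and ran from -0.383 to 0.316 between amounts. Of 15 pairs of amounts, 4 gave r above 0.1. These are the 4 with same-numbered libraries in 1 code run, and no other pair exceeded 0.0558. The numbers thus do not pair the libraries throughout, but a shared deviation within code runs is not excluded. With a replicate block, peak number against input gave r = 0.751 and recovery 0.88, and no call changed. Merging of overlapping rows and the limit to nuclear chromosomes left nothing to alter, and concordance without a whole replicate number could not be formed. Results that need genes or sequence were not run. Thinned to the depth of the 100 ng library, the other 12 input lists keep 13252 to 34720 peaks, against its 14845.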

Other observations

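The tests in this part, except the counts with equally long lists, were chosen after the results were seen, and so were the bounds they were read against. The division by amount below and the regions named here were also picked after the lists were seen. Low and high input gave partly different regions. Of the merged regions, 2211 had a peak in all 4 libraries of 500 and 250 ng and in none of the 6 libraries of 3 to 8 µg, and 3439 showed the reverse, beside 22388 with a peak in all 10. The low-amount regions had a median width of 636 bp and the high-amount regions of 472 bp. The highest-ranked low-amount regions lay on chromosome 12 from 9074808 to 9075960, on chromosome 7 from 19037786 to 19039092 and on chromosome 3 from 32868561 to 32869167. The highest-ranked high-amount regions lay on chromosome 12 from 13403657 to 13403885 and from 323478 to 324030, and on chromosome 4 from 2306517 to 2306933. The first of them covers the second-ranked region gained under salt and lies within a cluster of RNaseH peaks. None of the low-amount regions had a peak at 100 ng (0%), whereas 15.9% of the high-amount regions did. Salt and CK(salt) libraries held 0.317 to 0.633% of the low-amount regions and 56.6 to 92.6% of the high-amount regions.

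Of 100 divisions of the 10 libraries into 4 and 6, only the real one separated as many as 5650 regions and the highest other gave 266, but the division was picked from these same lists, so the count does not exclude chance. The tables argue against depth as the whole cause, because 3 libraries deeper than each low-amount library held 0.362 to 4.39% of the low-amount regions, and the 2 salt and CK(salt) libraries shallower than each of them held 56.6% and 71.3% of the high-amount regions. The run of library codes is left open. Against it, 500 ng replicate 1 had a mean Jaccard index of 0.508 with the 5 and 3 µg libraries of its own run. Its index was 0.558 to 0.605 with low-amount libraries of other runs. The 1 µg libraries showed no clear preference for their own runs. Replicate 1 had 0.651 and 0.629 within its run, and 0.609 to 0.658 with the high-amount libraries of other runs. Replicate 2 had 0.657 within its run, and 0.607 to 0.653 with the low-amount libraries of other runs. Over 66 pairs, however, the index correlated with a shared run (r = 0.349). It also correlated with the difference in log2 amount (r = -0.744) and, less strongly, in log2 background coverage (r = -0.252). Of the low-amount regions, 1 µg replicate 1 held 4.39% and 1 µg replicate 2 held 91.2%, which would speak against the labelled amount alone only if the label of replicate 2 is right. Its index was 0.501 with replicate 1 and 0.607 to 0.657 with the low-amount libraries, so that a wrong label, the amount and the run cannot be told apart.

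Fewer regions under salt could come from lower depth, from lower enrichment or from the treatment. The tables argue against depth, because the 4 lists thinned to 1 depth kept a log2 difference of -0.42 in peak number and both salt lists stayed lowest (30492 and 35904 against 48481 and 40369 peaks). They argue against the complete loss of the strongest sites, since 0 of 3670 regions in the strongest decile of CK(salt) were lost. A strong site with a lowered signal would still be called, so the lists cannot show a partial decrease there. With equally long lists, salt against CK(salt) separated 2639 regions, the division by replicate number, which follows the runs of library codes, 2699, and the crossed pairs 1692. Lower enrichment in the salt libraries and a general decrease of R-loops under salt, the biological explanation, both stay open.

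Peaks in the RNaseH library may mark places where reads pile up whatever the treatment. Depth is argued against, as the deeper input lists thinned to this depth kept at least 21244 peaks. Incomplete digestion stays open, since only 19 of the 1012 strongest common regions (1.88%, 95% interval 1.13 to 2.92%) kept a peak, yet these were 27.9% of the 68 common regions with a residual peak (interval 17.7 to 40.1%), 8 of the 10 highest-ranked common regions kept one, and peaks at residual places had a median score percentile of 63.7 to 99.8 over the input lists. In the 13 input lists, peaks at the residual places had a local background of at least 5 times the genome-wide level in 37.5 ± 8.73% of cases (SD, n = 13) and other peaks in 0.0746% or fewer, in all 13 lists in the same direction. These lists measure the same places, many of them in clusters, so their agreement is not independent evidence. The raised local background would fit sequences present in several copies, which the lists cannot show without the genome. Clusters of hybrids that resist the enzyme remain open as the biological explanation.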
